A study of Homo sapiens with 12 samples.

How the data were processed

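Values were taken as deposited: 1 value per probe set on each of 12 arrays, read as log2 intensities because their range and shape fit no linear scale. The submitters' processing notes name MAS5 for the signal and give neither the base of the logarithm nor a normalization. The 4 replicate 1 arrays share one distribution (medians 6.85 to 6.88) and the 8 others another (6.38 to 6.45), so comparisons rest on differences within each set. Raw intensity files were not analysed here, so background, summarization and spatial faults were not examined.

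For each array 2 was raised to the power of every value, and the resulting signal was scaled to a 2% trimmed mean of 500, and taken to log2 after adding 32. Scale factors were 1.16 to 1.23 on replicate 1 and 1.62 to 1.78 on the others. The median over genes of each difference stayed within 0.0559 of zero under every scaling tried, and no global shift was read. Scaling, and the shared distributions of the deposited values, bring the arrays of a set to a common level. A global shift could therefore not have been seen. Of 49395 probe sets, 102 controls were left out; 44988 named 1 gene by the platform annotation, 1832 named several and 2473 none. Names were matched to the current human gene table by gene identifier for 44961 probe sets. Of 18132 genes, each represented by its brightest probe set, 12715 with a signal of at least 100 on at least 3 arrays were tested, and 12105 on replicates 2 and 3 alone. Probe sets naming several genes were never named in the text.

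Differential expression was tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 7 residual degrees of freedom, or 4 for replicates 2 and 3), with 1 term for each of the 4 groups and 1 for the labelled set, and p-values adjusted by Benjamini-Hochberg at 0.05. Contrasts were CANT1 minus wild type in each line, their average, their difference, and OCM1 minus MUM2B in wild type cells. The median standard error was 0.183 for a single line, 0.129 for the average and 0.259 for the difference. Gene lists were tested with camera at a preset correlation of 0.01 and again with an estimated correlation, adjusted over 31 lists. Apart from those stated below as added or chosen after the data were seen, tests, alternatives, lists and the rule for naming genes were fixed before the data were examined.

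The rule named the 8 largest increases and decreases that passed with the same direction in both labelled sets (5 and 5 for the difference and for the wild type lines), or, where none passed, the 5 smallest p-values in each direction as not passing. It added every measured gene around CASC15 and of the X inactivation list, and up to 4 members of each list described. Genes chosen from replicates 2 and 3 were added after the values were seen. Lists covered G1/S, G2/M, p53 targets, apoptosis, interferon response, antigen presentation, NF-κB, MAPK outputs, YAP targets, hypoxia, the unfolded protein response, cholesterol synthesis, heat shock, immediate early genes, ribosomal proteins, the respiratory chain, cancer testis genes, angiogenesis, invasion, Wnt and TGF-β components, polycomb genes, the uveal melanoma class genes, mesenchymal genes, and markers of pigment, epithelial, immune, endothelial, fibroblast and neural crest cells.

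Alternatives covered quantile normalization, a smaller and a larger offset, a floor, no filter or a stricter one, no set term, a replicate block, replicates 2 and 3 only, only the arrays compared, an intensity trend, array weights, all probe sets, a 2-fold threshold and each array left out. For named genes, the fits on only the arrays compared and without probe sets ending in _x_at or _s_at were added after the results were seen. The labels name the controls of all 3 replicates as wild type cells and describe no empty vector, so the CANT1 contrasts do not separate an effect of CANT1 from one of vector or selection.

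On simulated arrays with 200 changed genes, in 5 runs, the 12-array model found 59.4% of MUM2B and 61.2% of OCM1 changes of log2 1, and 90.6% and 90.0% of those of log2 2. For the average it found 80.0% and 96.4%, for the difference 34.0% and 76.6%. False calls made up 4.22% to 6.37%. A planted G1/S decrease of 0.5 in OCM1 was called in 5 of 5 runs, with 0 other lists called. The simulated noise was drawn independently for each gene and array. These runs therefore do not give the error rate where genes are correlated or where an array stands apart.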

Results

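Gene expression was measured on 12 Affymetrix PrimeView arrays from 2 uveal melanoma cell lines, MUM2B and OCM1. In each line, cells overexpressing the long noncoding RNA CANT1, a transcript of the CASC15 locus, were compared with wild type cells, at 3 arrays per group. The small number of arrays limits precision. The replicate 1 arrays carry a growth label with puromycin and replicates 2 and 3 a label with serum-containing medium, so each group is divided into 1 and 2 arrays. The labels do not say that the replicates are separate cultures, so every p-value here measures only the spread between arrays, which may be technical. Replicates 2 and 3 of the same group correlated at r = 0.994 to 0.996 across genes. Differences are log2 values of scaled signal plus 32, which understates the fold of dim genes, and ± stands for the standard error unless SD is written.

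The overexpressed RNA itself could not be followed. CASC15 has 1 probe set, with a signal of 12.9 to 17.9 over the 12 arrays. That probe set need not lie in the CANT1 transcript, so it checks nothing. Of the genes around CASC15, none passed in either line with all arrays. SOX4, a transcription factor gene beside it, was at 0.28 ± 0.29 in MUM2B and −0.33 ± 0.29 in OCM1 (limma adjusted p = 1.00 and 0.761). CDKAL1 (−0.013 ± 0.21 and 0.18 ± 0.21), E2F3 (0.14 ± 0.27 and −0.20 ± 0.27), MBOAT1 (0.22 ± 0.39 and 0.76 ± 0.39) and DCDC2 (0.18 ± 0.19 and −0.025 ± 0.19) did not pass either. The X inactivation genes CHIC1 (−0.23 ± 0.12 in MUM2B and −0.070 ± 0.12 in OCM1), SMCHD1 (−0.098 ± 0.11 and 0.011 ± 0.11), LRIF1 (−0.14 ± 0.32 and −0.48 ± 0.32) and PUDP (−0.050 ± 0.13 and 0.26 ± 0.13) stayed below the threshold too. XIST, the RNA that coats the inactive X chromosome, had the widest spread of these genes, at 1.92 ± 2.54 in MUM2B and 1.03 ± 2.54 in OCM1.

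OCM1 cells overexpressing CANT1 gained transcripts of APOC2, an apolipoprotein that activates lipoprotein lipase, and of SFRP1, a secreted antagonist of Wnt ligands. APOC2 rose 12.4-fold (log2 3.63 ± 0.22, limma adjusted p = 0.000171, n = 3 arrays per group), from a level of 7.18 ± 0.33 SD to 10.81 ± 0.41 SD. SFRP1 rose 12.1-fold (3.59 ± 0.30, adjusted p = 0.00147) from 8.03 ± 1.25 SD to 11.63 ± 0.52 SD, near the 12.42 ± 0.50 SD of wild type MUM2B. The follistatin-like gene FSTL5 rose by 2.03 ± 0.12 (adjusted p = 0.000171) and the neurofilament gene NEFL by 1.79 ± 0.15 (adjusted p = 0.00162). AMPH, which encodes the endocytic protein amphiphysin, fell by 1.58 ± 0.11 (adjusted p = 0.000525), from 8.91 ± 0.27 SD to 7.33 ± 0.45 SD.

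In OCM1, limma called 13 genes up and 2 down among 12715 tested, and 11 of the increases and 1 decrease were at least 2-fold. All 15 had the same direction on the replicate 1 arrays, which are part of that fit. The extracellular proteins among the increases included EMILIN1 (1.81 ± 0.24, limma adjusted p = 0.0306) and the aggrecan protease ADAMTS4 (1.42 ± 0.19, adjusted p = 0.0306). HSBP1L1 (1.95 ± 0.18, adjusted p = 0.00307) and the septin-binding gene CDC42EP3 (1.64 ± 0.19, adjusted p = 0.0164) rose as well, while PURB, a single-strand nucleic acid binding gene, fell by 0.83 ± 0.12 (adjusted p = 0.0476). With only the OCM1 arrays in the fit all of these genes were lost by limma, APOC2, FSTL5, NEFL and SFRP1 at adjusted p = 0.0647 and HSBP1L1 at 0.121. In the other alternatives that tested them, APOC2 was called in 25, FSTL5 in 22 and HSBP1L1 and NEFL in 27 each, without a loss. The filter on dim genes kept FSTL5 out whenever an OCM1 CANT1 array was left out. It also kept APOC2 out of the fit on replicates 2 and 3 alone, so neither gene was tested without the replicate 1 arrays. AMPH and SFRP1 were lost in 2 of 28 alternatives each, CDC42EP3 in 8 of 28, EMILIN1 in 11 of 28, ADAMTS4 in 13 of 27 and PURB in 15 of 28. Their adjusted p reached 0.0679, 0.0647, 0.157, 0.232, 0.221 and 0.872. Over the alternatives the log2 effect ran from 1.07 to 3.11 for FSTL5, 2.401 to 3.84 for SFRP1, 2.97 to 4.01 for APOC2, 1.69 to 1.88 for NEFL, 1.51 to 2.17 for HSBP1L1 and −1.83 to −1.16 for AMPH. For EMILIN1 it ran from 1.20 to 2.11, for CDC42EP3 from 1.44 to 1.91, for ADAMTS4 from 1.01 to 1.66 and for PURB from −0.90 to −0.16. Probe sets of several genes were unequal. In replicates 2 and 3, the 2 for AMPH read −1.68 and −0.23 and the 2 for ADAMTS4 1.07 and 0.11. The 4 for SFRP1 ran from 1.73 to 3.17 and the 3 for PURB from −0.69 to −0.17, while the 3 for NEFL lay between 1.87 and 2.28. The probe sets used for APOC2, EMILIN1, ADAMTS4, SFRP1 and PURB are of a kind that can bind related transcripts.

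**Figure D1:**
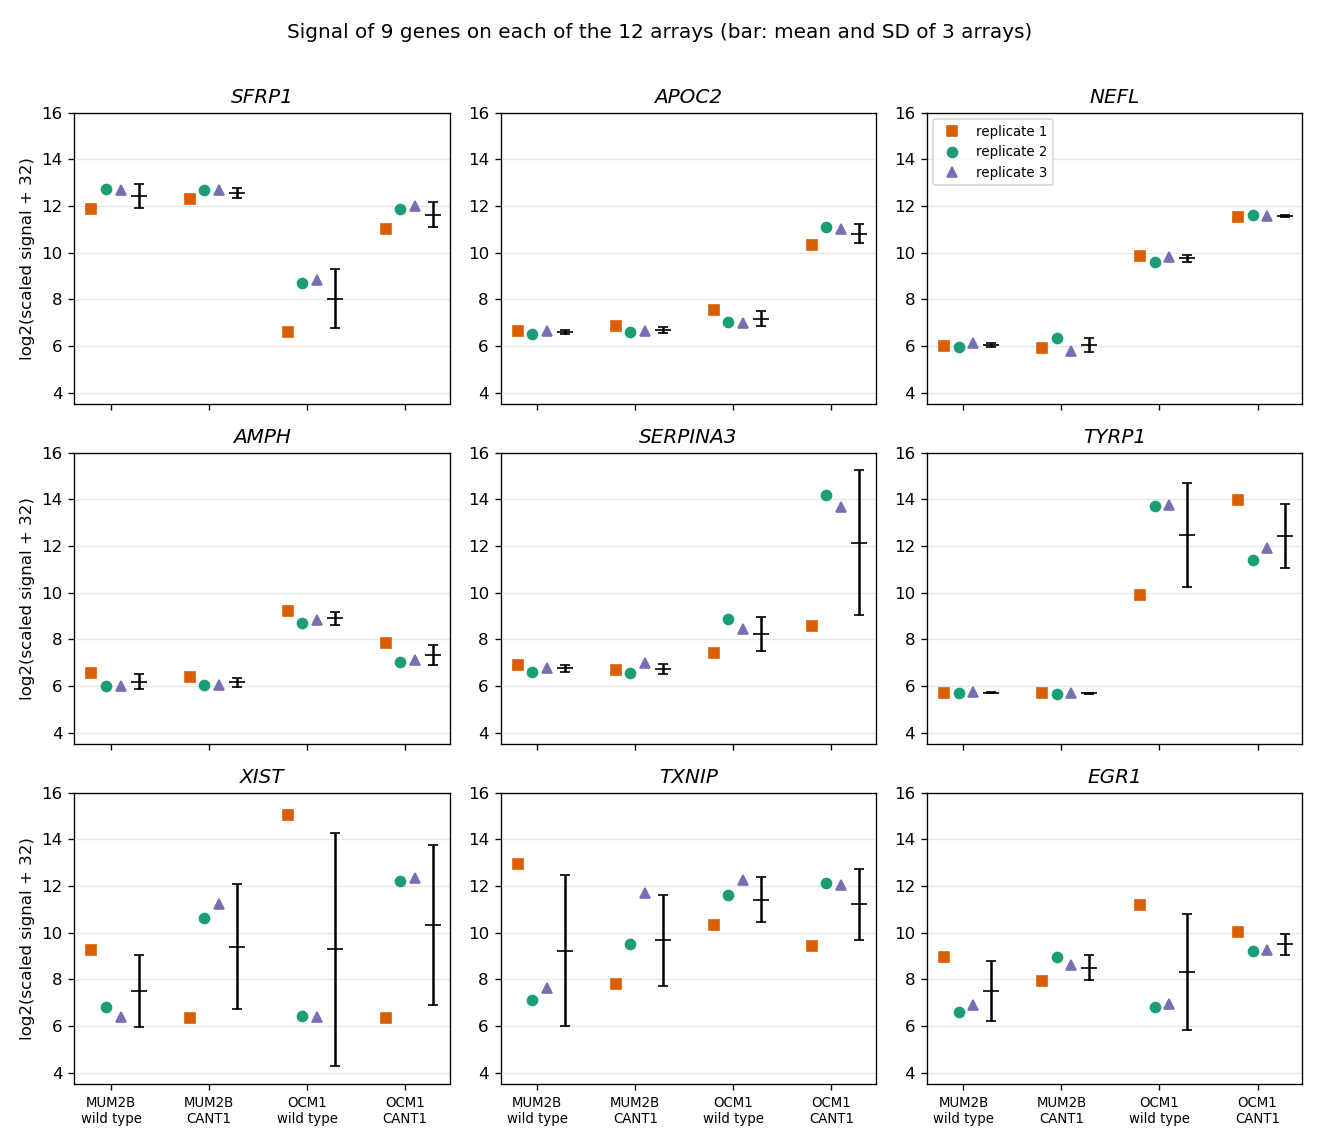
Level of 9 genes on each of the 12 arrays, as log2 of scaled signal plus 32, by cell line and by wild type or CANT1; points are single arrays coloured by replicate number, and black bars give the mean ± SD of 3 arrays. SFRP1 and APOC2 rise with CANT1 on every OCM1 array, whereas XIST reaches 15.04 on the wild type replicate 1 array and 12.22 and 12.35 on CANT1 replicates 2 and 3.

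Gene lists moved in OCM1 without single members passing. The camera test with preset correlation called 10 of 31 lists, 6 up and 4 down, and with an estimated correlation none held. Pigment cell genes were higher (adjusted p = 0.000102; adjusted p = 0.989 with an estimated correlation), at a median of 0.78 with 24 of 26 members above zero. That median was 2.77 on replicate 1, whose wild type array stood apart, and −0.11 on replicates 2 and 3. EDNRB, a receptor of the melanocyte lineage, stood at 1.78 ± 0.61, from 4.23 on replicate 1 and 0.56 on replicates 2 and 3. The lineage factor MITF stood at 1.38 ± 0.61, from 3.46 and 0.34. Outputs of the MAPK pathway (adjusted p = 0.00172), interferon response genes (adjusted p = 7.97e-05) and antigen presentation genes (adjusted p = 6.68e-05) were higher as well, all with adjusted p = 0.989 with an estimated correlation. DUSP6, a feedback phosphatase of ERK, stood at 1.70 ± 0.54 (3.49 on replicate 1 and 0.80 on replicates 2 and 3), BST2, which tethers budding virus, at 2.69 ± 0.44, and HLA-DMB at 1.29 ± 0.30. Invasion genes (list adjusted p = 0.00841) and respiratory chain genes (list adjusted p = 0.00905) completed the higher lists, again with adjusted p = 0.989 with an estimated correlation. The integrin ITGA3 stood at 0.89 ± 0.15 (limma adjusted p = 0.0831). On replicates 2 and 3 camera called neither list (adjusted p = 0.915 and 0.312).

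Proliferation genes made up the lower lists in OCM1, together with sterol synthesis and ribosomal protein genes. G2/M genes had a median of −0.30 with 3 of 36 members above zero (camera adjusted p = 1.70e-06), and UBE2C and TTK stood at −1.18 ± 0.28 and −0.69 ± 0.14. G1/S genes (median −0.34, adjusted p = 0.00324), cholesterol synthesis genes (median −0.35, adjusted p = 0.000149) and ribosomal protein genes (median −0.078, adjusted p = 0.0205) followed, and the 4 lists all had adjusted p = 0.989 with an estimated correlation. Ribosomal protein genes changed sign on replicates 2 and 3 (adjusted p = 0.783). INSIG1, the sterol-regulated retention factor, stood at −1.57 ± 0.41. By limma over all genes, 0 members of the 10 lists passed. At unadjusted p under 0.05, 7 MAPK outputs were higher and 1 lower, 4 members were higher in each of the pigment, invasion, interferon and antigen presentation lists, and 6 G2/M and 3 cholesterol genes were lower. Adjusted over the list alone, 2 G2/M genes fell, and 1 gene each rose among the invasion, interferon and antigen presentation lists. The other 21 lists had adjusted p from 0.114 to 0.983. Among these the median, mean and test differed in sign for the genes around CASC15, NF-κB, unfolded protein response, immediate early, angiogenesis, Wnt and TGF-β, endothelial and neural crest genes.

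The OCM1 call depended on the replicate 1 arrays. Each of the 12 arrays moved the count of 15 by more than 1.5 times when left out, from 5 without either CANT1 array of replicates 2 and 3 to 139 without wild type replicate 1. On replicates 2 and 3 alone, 2 arrays per group, limma called 1656 genes up and 1166 down, and 1109 of the 2822 (39.3%) had the same sign on replicate 1. The wild type replicate 1 array of OCM1 stood apart, with a mean correlation of 0.828 with the other OCM1 arrays against 0.936 to 0.978 for every other array with its own line. The 3′ to 5′ signal of ACTB, an RNA quality measure, moved with CANT1 in OCM1, in opposite senses in the 2 sets. It was log2 0.909 and 0.843 on CANT1 against 0.749 and 0.664 on wild type arrays in replicates 2 and 3, and 2.29 against 2.49 on replicate 1.

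Chosen after the values of replicates 2 and 3 were seen, the largest OCM1 increases there were of XIST (5.88 ± 0.18, limma adjusted p = 1.05e-08) and SERPINA3, a secreted serine protease inhibitor (5.29 ± 0.19, adjusted p = 3.29e-08). On replicate 1 the XIST difference was −8.68 and that of SERPINA3 1.14. SYTL2, an adaptor of melanosome and vesicle transport, rose by 4.83 ± 0.11 against −6.17 on replicate 1, and CA2 (2.75 ± 0.14 against −6.34) and UCHL1 (2.68 ± 0.10 against −7.27) showed the same contrast. BST2 (3.53 ± 0.11 and 1.00) and ALDH1A3, a retinaldehyde dehydrogenase (2.63 ± 0.10 and 2.95), were higher in both sets. TYRP1, a melanosome enzyme, fell by 2.11 ± 0.14 (adjusted p = 2.98e-06) but was 4.08 higher on replicate 1. VEPH1 (−1.59 ± 0.12 and 2.13) and TNFAIP6 (−1.52 ± 0.14 and 2.18) did likewise. INSIG1 fell in both (−1.53 ± 0.21 and −1.64), and OLFML2A (−1.52 ± 0.14 and −0.85) and FHDC1 (−1.43 ± 0.14 and −0.25) kept their direction. The small nucleolar RNA SNORD17 read −1.39 ± 0.15 and 0.42. The 5 probe sets of XIST ranged from 1.90 to 5.88, the 3 of VEPH1 from −1.59 to 0.11 and the 2 of OLFML2A from −1.52 to −0.073. Those of BST2 ranged from 0.059 to 3.53, of SYTL2 from 1.40 to 4.83, of UCHL1 from 0.53 to 2.71 and of ALDH1A3 from 0.32 to 2.85.

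Cell cycle genes fell together on the OCM1 arrays of replicates 2 and 3, where camera called 7 lists and none with an estimated correlation. Of 36 G2/M genes 24 fell and 0 rose, 25 over the list alone (adjusted p = 1.89e-12; adjusted p = 0.475 with an estimated correlation), among them UBE2C (−1.01 ± 0.10), CENPF (−0.85 ± 0.09) and MKI67 (−0.60 ± 0.09). Of 33 G1/S genes 16 fell (adjusted p = 4.48e-09; adjusted p = 0.596 with an estimated correlation), including the replication licensing genes MCM7 (−0.71 ± 0.10) and MCM5 (−0.76 ± 0.12). Cholesterol synthesis genes fell in 13 of 22 cases (adjusted p = 5.08e-07; adjusted p = 0.475 with an estimated correlation), with EBP at −0.87 ± 0.11. Heat shock genes fell in 10 of 19 (adjusted p = 0.000164; adjusted p = 0.475 with an estimated correlation), with HSPA8 at −0.84 ± 0.09, while the cochaperone BAG3 rose by 1.06 ± 0.10. Interferon response genes rose in 11 of 31 (adjusted p = 0.000409) and antigen presentation genes in 9 of 21 (adjusted p = 0.0129), with IFITM1 at 1.14 ± 0.15 and HLA-B at 1.49 ± 0.16. MAPK outputs rose in 11 of 24 and fell in 2 (adjusted p = 0.0129). These 3 lists also had adjusted p = 0.475 with an estimated correlation. EGR1, an immediate early target of ERK, rose by 2.35 ± 0.13 and the cyclin gene CCND1 by 0.84 ± 0.10, whereas MYC fell by 0.77 ± 0.11. Pigment cell genes were not called here (median −0.11, adjusted p = 0.133) and were 2.77 higher on replicate 1.

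In MUM2B no gene passed when all arrays were used. Limma called 0 of 12715, with 220 at unadjusted p under 0.05, in a fit where the 2 labelled sets run in opposite directions. The smallest p-values belonged to genes that did not pass. HSD17B2, which inactivates estradiol, was at 1.04 ± 0.15 and the transmembrane protein gene TMEM200A at 1.09 ± 0.16 (limma adjusted p = 0.431 each), and both were higher with CANT1 on replicate 1 too (0.70 and 1.55). CCNA1 (0.84 ± 0.16), CRIP1 (0.67 ± 0.13) and HTRA2 (0.47 ± 0.10) stood on the higher side (adjusted p = 1.00 each). On the lower side were DAPK1 (−0.63 ± 0.14), BDNF (−0.46 ± 0.11), KRT80 (−0.69 ± 0.17), SKIL (−0.55 ± 0.14) and SLC3A2 (−0.55 ± 0.15, adjusted p = 1.00 each). SFRP1, already high, stood at 12.42 ± 0.50 SD and 12.56 ± 0.22 SD.

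By camera 6 lists were higher in MUM2B with 0 members passing by limma, and none of them with an estimated correlation. G2/M, interferon response, NF-κB and MAPK output genes shared an adjusted p = 0.000506 (adjusted p = 0.680 with an estimated correlation), at medians of 0.14, 0.26, 0.24 and 0.24. Invasion genes (adjusted p = 0.0424; adjusted p = 0.805 with an estimated correlation) and mesenchymal genes (adjusted p = 0.0499; adjusted p = 0.680 with an estimated correlation) followed. The collagen gene COL6A3, at 1.40 ± 0.31, was the 1 member that rose over its list alone. At unadjusted p under 0.05, 3 mesenchymal, 2 NF-κB and 1 G2/M gene were higher. On replicates 2 and 3 the G2/M list changed sign (adjusted p = 0.115). On replicate 1 the medians were 0.60 for G2/M genes but −0.33, −0.49 and −0.22 for interferon, NF-κB and MAPK genes. The other 25 lists had adjusted p from 0.0770 to 0.957. Among them median, mean and test differed in sign for X inactivation, pigment, immediate early, respiratory chain, fibroblast, neural crest and polycomb genes.

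The MUM2B arrays of replicates 2 and 3 differed strongly from wild type, in a direction opposite to that of replicate 1. Limma on those arrays alone, 2 per group, called 1741 genes up and 1291 down, and 380 of the 3032 (12.5%) had the same sign on replicate 1. Across genes, which are not independent replicates, the replicate 1 difference correlated at r = −0.618 with the effect in replicates 2 and 3 in MUM2B and at r = −0.220 in OCM1. Left out singly, 11 of the arrays kept the MUM2B count at 0 and MUM2B wild type replicate 1 raised it to 9. The sets also differed in the 3′ to 5′ signal of ACTB, at log2 2.14 to 2.49 on replicate 1 and 0.472 to 0.909 on replicates 2 and 3. In MUM2B it was 2.32 on wild type and 2.14 on CANT1 replicate 1, and 0.549 and 0.472 on wild type against 0.525 and 0.583 on CANT1 replicates 2 and 3.

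**Figure D2:**
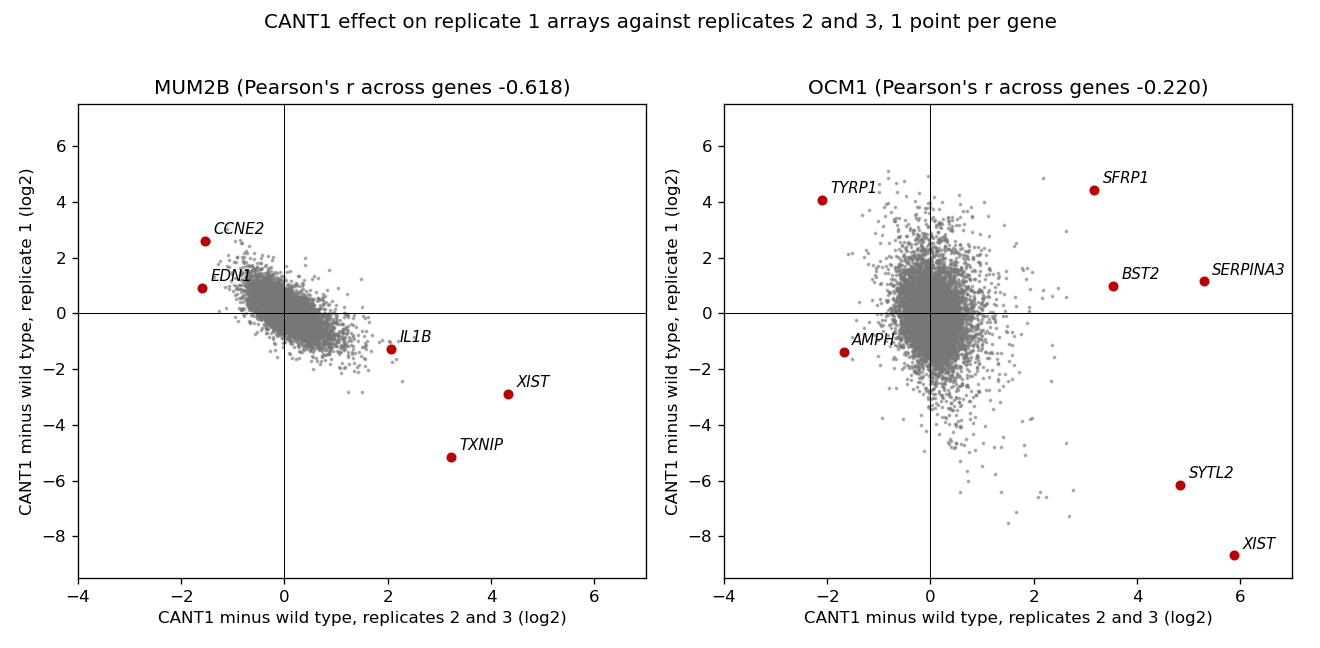
CANT1 minus wild type in replicates 2 and 3 (horizontal axis, log2) against the same difference on replicate 1 (vertical axis, log2), for MUM2B and OCM1; each point is a gene and named genes are red. The MUM2B cloud slopes downwards (r = −0.618), and in OCM1 (r = −0.220) SFRP1 lies high on both axes while XIST lies at opposite ends of them.

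Chosen after the values were seen, the largest MUM2B increases of replicates 2 and 3 were of XIST (4.33 ± 0.18, limma adjusted p = 9.15e-07), against −2.89 on replicate 1, and of TXNIP, an inhibitor of thioredoxin and glucose uptake (3.22 ± 0.50, adjusted p = 0.00157), against −5.14. The urea transporter SLC14A1 rose by 2.499 ± 0.15 (replicate 1 −0.85), the glucocorticoid-induced factor KLF9 by 2.28 ± 0.30 (−2.41) and HSD11B1, which makes cortisol, by 2.20 ± 0.21 (−0.98). MTSS1 (2.17 ± 0.15 and −1.64), the plasminogen activator PLAT (2.09 ± 0.23 and −1.76) and IL1B (2.07 ± 0.19 and −1.27) followed. Decreases included endothelin EDN1 (−1.60 ± 0.17 and 0.92 on replicate 1), the S-phase cyclin CCNE2 (−1.53 ± 0.23 and 2.61) and FAM111B (−1.45 ± 0.22 and 2.60). Further decreases were of RPL27A (−1.36 ± 0.09 and 1.29), MRPL1 (−1.29 ± 0.17 and 1.78), IGFBP3 (−1.27 ± 0.19 and 0.08), DLEU2 (−1.25 ± 0.12 and 1.88) and TRIM7 (−1.15 ± 0.13 and 0.95). The 5 probe sets of XIST ranged from 0.86 to 4.33, the 4 of KLF9 from 0.09 to 2.28, the 3 of TRIM7 from −1.15 to 0.16 and the 3 of DLEU2 from −1.25 to −0.00028.

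DNA replication genes fell in MUM2B in replicates 2 and 3, where camera called 10 lists and none with an estimated correlation. Of 33 G1/S genes 24 fell, 28 over the list alone (adjusted p = 2.20e-12; adjusted p = 0.349 with an estimated correlation), including GINS2 (−1.12 ± 0.20) and UNG (−0.85 ± 0.14). Their median was −0.58 here and 1.47 on replicate 1. NF-κB genes rose in 14 of 21 (adjusted p = 3.28e-08; adjusted p = 0.258 with an estimated correlation), with the chemokine CXCL8 at 1.68 ± 0.11 and the inhibitor NFKBIA at 0.85 ± 0.10. Interferon response genes rose in 16 of 31 (adjusted p = 2.43e-08; adjusted p = 0.349 with an estimated correlation), with ISG20 at 1.58 ± 0.12 and PSMB9 at 1.53 ± 0.17. MAPK outputs rose in 14 of 24 (adjusted p = 2.46e-08) and antigen presentation genes in 8 of 21 (adjusted p = 0.000382), both with adjusted p = 0.258 with an estimated correlation. EGR1 rose by 2.04 ± 0.13 and HLA-B by 1.35 ± 0.16. Cholesterol synthesis genes rose in 16 of 22 and fell in 1 (adjusted p = 5.60e-06; adjusted p = 0.349 with an estimated correlation), HMGCS1 by 1.30 ± 0.21. Invasion genes rose in 11 of 30, 21 over the list alone with 1 fall (adjusted p = 6.17e-05; adjusted p = 0.349 with an estimated correlation), with the integrin ITGB3 at 1.35 ± 0.20 and the gelatinase MMP2 at 1.34 ± 0.20. Mesenchymal genes rose in 7 of 26 and fell in 1 (adjusted p = 0.0490; adjusted p = 0.349 with an estimated correlation), with the fibronectin gene FN1 at 1.22 ± 0.18. Uveal melanoma class genes rose in 8 of 11 (adjusted p = 0.000124) and Wnt and TGF-β components rose in 13 of 31 and fell in 2 (adjusted p = 0.0216), both with adjusted p = 0.349 with an estimated correlation. The BMP-responsive genes ID4 and ID3 stood at 0.99 ± 0.10 and −0.98 ± 0.11. SOX4, beside CASC15, rose by 0.52 ± 0.11 in MUM2B (adjusted p = 0.00564) with −0.19 on replicate 1, and stood at 0.22 ± 0.11 in OCM1 (adjusted p = 0.163).

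**Figure D3:**
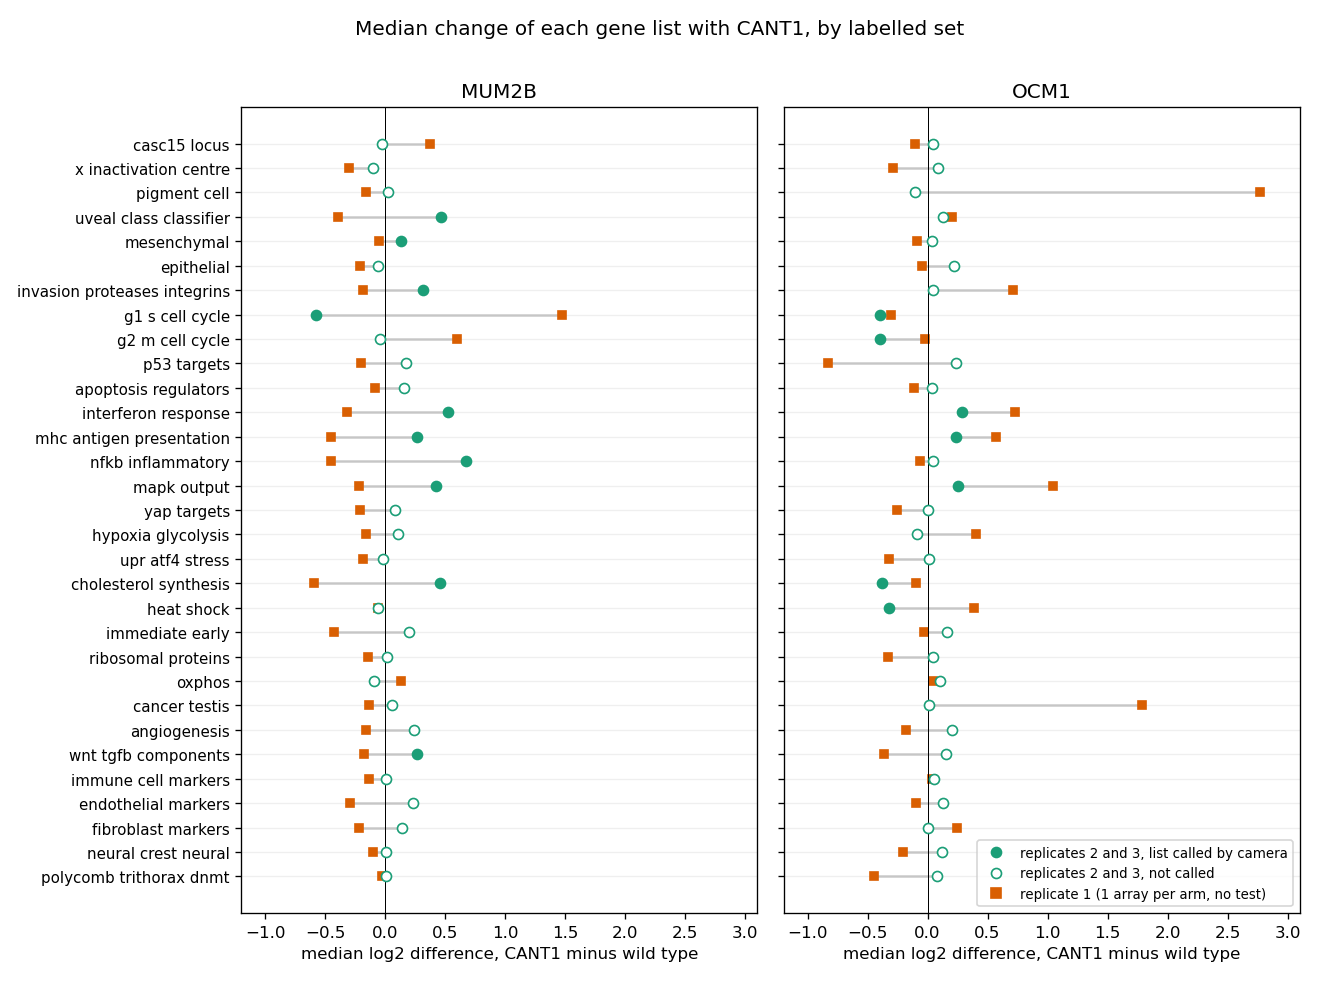
Median log2 difference, CANT1 minus wild type, of each of the 31 gene lists in MUM2B and OCM1; green circles are replicates 2 and 3, filled where camera called the list, and orange squares are replicate 1. G1/S genes in MUM2B lie at −0.58 in replicates 2 and 3 and at 1.47 on replicate 1, and pigment cell genes in OCM1 at −0.11 and 2.77.

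Averaged over both lines, 4 genes were higher with CANT1, SFRP1 (1.86 ± 0.21, limma adjusted p = 0.0224), APOC2 (1.86 ± 0.16, adjusted p = 0.00319), FSTL5 (1.02 ± 0.08, adjusted p = 0.00319) and NEFL (0.90 ± 0.11, adjusted p = 0.0337). AMPH was lower (−0.80 ± 0.08, adjusted p = 0.0103). These 5 genes are the OCM1 genes again, with no MUM2B change behind them. At least 5 genes were called in 18 of 200 splits of the same arrays, the real one included, so chance is not excluded. APOC2 was called in the 25 alternatives that tested it and FSTL5 in its 22, none of which leaves out an OCM1 CANT1 array, by limma at adjusted p up to 0.0392 and 0.0254. Neither gene was tested on replicates 2 and 3 alone. AMPH, NEFL and SFRP1 were lost in 6, 12 and 13 of 27, reaching 0.795, 0.323 and 0.691. Interferon response genes had the lowest list p, with 29 of 32 members above zero (camera adjusted p = 2.03e-07; adjusted p = 0.923 with an estimated correlation) and MAPK outputs the next (adjusted p = 3.94e-06). Invasion (adjusted p = 0.000626), antigen presentation (adjusted p = 0.000122) and pigment genes (adjusted p = 0.000668) were higher too. G2/M (adjusted p = 0.04999), cholesterol (adjusted p = 0.0400) and ribosomal protein genes (adjusted p = 0.00269) were lower, and all 8 lists had adjusted p = 0.923 with an estimated correlation. The pigment and ribosomal protein lists changed sign on replicates 2 and 3 (adjusted p = 0.796 and 0.837). Median, mean and test differed in sign among lists not called for X inactivation, apoptosis, YAP, angiogenesis, Wnt and TGF-β, immune and neural crest genes. Left out singly, MUM2B wild type replicate 1 raised the count of 5 to 177, OCM1 wild type replicate 1 to 45 and OCM1 CANT1 replicate 1 to 8. It fell to 3 without MUM2B CANT1 replicate 1, to 2 without MUM2B wild type replicate 2 or 3 or OCM1 wild type replicate 2, and to 1 without OCM1 CANT1 replicate 2 or 3.

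In replicates 2 and 3 more genes changed in the same direction in both lines than independent lists would share. Of genes called there, 399 rose in both lines against 238 expected of independent lists and 223 fell in both against 124, while 156 rose in MUM2B and fell in OCM1 against 168 expected. Such an expectation treats genes as independent. The overlap does not separate CANT1 from vector or selection, or from the admixture weighed below. EGR1 rose by 2.19 ± 0.09 on average (limma adjusted p = 2.40e-07; replicate 1 −1.09) and XIST by 5.10 ± 0.13 (adjusted p = 3.40e-09; replicate 1 −5.79). G1/S genes fell in 31 of 33 cases on average (camera adjusted p = 1.5e-16; adjusted p = 0.385 with an estimated correlation), CDC45 by 0.74 and UNG by 0.79. Across genes the effects of the 2 lines correlated at r = 0.146 in replicates 2 and 3, r = 0.109 on replicate 1 and r = 0.0466 with all arrays, the genes not being independent replicates. Left out singly, arrays moved that last value from −0.252 without MUM2B CANT1 replicate 1 to 0.265 without MUM2B wild type replicate 1. It was −0.135 and −0.121 without MUM2B wild type replicate 2 or 3, and 0.215 without MUM2B CANT1 replicate 3.

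The response differed between the lines in 6 genes by the test of the difference itself, all of them changed in OCM1. At least 6 genes were called in 11 of 200 splits of the same arrays, the real one included, so chance is not excluded. APOC2 differed by 3.54 ± 0.31 (limma adjusted p = 0.00504), SFRP1 by 3.46 ± 0.42 (adjusted p = 0.0281) and HSBP1L1 by 2.26 ± 0.26 (adjusted p = 0.0255). FSTL5 differed by 2.01 ± 0.17 (adjusted p = 0.00504), NEFL by 1.80 ± 0.22 (adjusted p = 0.0281) and AMPH by −1.56 ± 0.16 (adjusted p = 0.0132). FSTL5 was called in the 22 alternatives that tested it, none of which leaves out an OCM1 CANT1 array, and APOC2 in 24 of 25, by limma at adjusted p up to 0.0410 and 0.0596. Neither gene was tested on replicates 2 and 3 alone. HSBP1L1, NEFL, AMPH and SFRP1 were lost in 10, 13, 8 and 15 of 27, reaching 0.172, 0.350, 0.809 and 0.772. Cholesterol synthesis genes stood lower in OCM1 than in MUM2B by this measure (median −0.45, camera adjusted p = 5.28e-05; adjusted p = 0.908 with an estimated correlation). So did G2/M (median −0.43, adjusted p = 6.53e-10) and G1/S genes (adjusted p = 0.00311). Pigment (adjusted p = 0.00334) and antigen presentation genes (adjusted p = 0.00437) stood higher, and these 4 lists too had adjusted p = 0.908 with an estimated correlation. On replicates 2 and 3 the pigment and G1/S lists changed sign (adjusted p = 0.0854 and 0.412) and antigen presentation genes were not called (adjusted p = 0.848). Median, mean and test differed in sign for X inactivation, uveal class, mesenchymal, hypoxia, unfolded protein response and neural crest genes, none of them called. On replicates 2 and 3 alone, 2650 genes differed. There the sterol genes INSIG1 (−2.65 ± 0.30), HMGCS1 (−2.27 ± 0.30) and MSMO1 (−2.02 ± 0.23) had a lower effect in OCM1, as did 15 of 22 members of their list (adjusted p = 1.88e-10; adjusted p = 0.586 with an estimated correlation). Single arrays moved the count of 6 to 15, 35 and 11 without MUM2B wild type, OCM1 wild type and OCM1 CANT1 replicate 1. It was 2 without MUM2B wild type replicate 2 or 3, MUM2B CANT1 replicate 3 or OCM1 wild type replicate 2, 3 without MUM2B CANT1 replicate 2, 1 without OCM1 CANT1 replicate 2 and 0 without OCM1 CANT1 replicate 3.

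The wild type lines differed from each other in their lineage programmes. OCM1 expressed the melanosome genes TYRP1 (6.76 ± 0.97, limma adjusted p = 0.000638), MLANA (6.65 ± 0.52, adjusted p = 1.37e-05) and PMEL (6.63 ± 0.28, adjusted p = 2.81e-07), with QPCT (6.46 ± 0.28) and the tumour antigen gene PRAME (6.43 ± 0.40, adjusted p = 2.70e-06). MLANA lay at 6.33 ± 0.21 SD in MUM2B and 12.98 ± 1.499 SD in OCM1. MUM2B expressed TGM2, a protein crosslinking enzyme (OCM1 minus MUM2B −7.70 ± 0.16, adjusted p = 9.04e-09), the receptor genes IL13RA2 (−7.38 ± 0.23, adjusted p = 4.39e-08) and AXL (−7.07 ± 0.20, adjusted p = 2.52e-08), the urokinase gene PLAU (−7.00 ± 0.26) and ESM1 (−6.93 ± 0.17). Limma called 2430 genes higher in OCM1 and 1765 lower, and 3936 of the 4195 (93.8%) had the same sign on replicate 1, which is part of that fit. Of the 7829 genes called on replicates 2 and 3 alone, 5022 (64.1%) had the same sign on replicate 1. The OCM1 wild type mean includes the replicate 1 array that stood apart, and on replicates 2 and 3 alone TYRP1 differed by 8.04 ± 0.14, MLANA by 7.57 ± 0.12, PRAME by 7.15 ± 0.11 and PMEL by 7.20 ± 0.09.

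Camera called 13 of 31 lists between the wild type lines, of which only YAP targets held with an estimated correlation. YAP targets were lower in OCM1 in 16 of 22 cases and higher in 1 (adjusted p = 2.12e-10; adjusted p = 0.00430 with an estimated correlation), with CCN1 at −6.20 ± 0.31 and CCN2 at −5.83 ± 0.27. On replicates 2 and 3 alone the estimated correlation gave adjusted p = 0.193. Pigment cell genes were higher in 23 of 26, all 26 over the list alone (adjusted p = 2.09e-09; adjusted p = 0.404 with an estimated correlation), including TFAP2A (4.01 ± 0.29) and PAX3 (3.58 ± 0.23). They held on replicates 2 and 3 (adjusted p = 0.0254 with an estimated correlation). NF-κB genes were lower in 13 of 22 and higher in 0 (adjusted p = 4.42e-07; adjusted p = 0.367 with an estimated correlation), IL1A by −5.72 ± 0.27 and CXCL1 by −4.57 ± 0.25. Epithelial genes were lower in 5 of 15 (adjusted p = 0.00382), mesenchymal genes in 12 of 26 (adjusted p = 0.000552) and endothelial genes in 7 of 12 (adjusted p = 9.85e-05). These 3 lists had adjusted p = 0.178 with an estimated correlation. Keratin KRT7 stood at −6.84 ± 0.30, the receptor TGFBR2 at −3.08 ± 0.14 and the cadherin CDH5 at −4.95. Angiogenesis genes were lower in 9 of 26 and higher in 3 (adjusted p = 0.0299; adjusted p = 0.367 with an estimated correlation), with NRP1 at −4.29. MAPK outputs were lower in 8 of 24 (adjusted p = 0.00382; adjusted p = 0.404 with an estimated correlation), with FOSL1 at −5.26 ± 0.25. Invasion genes, 8 of 31 lower (adjusted p = 0.0229), and interferon genes, 9 of 32 lower (adjusted p = 0.0427), had adjusted p = 0.799 with an estimated correlation. PLAUR stood at −2.89 and IFITM2 at −2.92. Both lists changed sign on replicates 2 and 3 (adjusted p = 0.747 and 0.823).

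Higher in OCM1 were also the uveal melanoma class genes, 7 of 11 (camera adjusted p = 0.0104; adjusted p = 0.367 with an estimated correlation), and cancer testis genes, 6 of 7 (adjusted p = 0.00177; adjusted p = 0.404 with an estimated correlation). MTUS1 stood at 3.14 ± 0.32 and MAGED2 at 2.32. Respiratory chain genes were higher in 15 of 34 and lower in 2 (adjusted p = 0.00382; adjusted p = 0.430 with an estimated correlation), with ATP5F1A at 0.93. The lists not called were apoptosis (adjusted p = 0.0664), cholesterol synthesis (0.0884), neural crest (0.0892), immediate early (0.0967), G2/M (0.148), Wnt and TGF-β (0.205) and heat shock genes (0.303). Nor were ribosomal protein (0.398), G1/S (0.401), antigen presentation (0.424), unfolded protein response (0.461), polycomb (0.498), hypoxia (0.579), fibroblast (0.690), immune (0.859) and p53 genes (0.946). Genes around CASC15 (0.807) and X inactivation genes (0.978) were not called either. These 2 lists, hypoxia and heat shock genes had a median, mean and test that differed in sign. Near CASC15, SOX4 was higher in OCM1 by 1.21 ± 0.29 (limma adjusted p = 0.0109) and DCDC2 lower by −4.06 ± 0.19 (adjusted p = 5.19e-07). Around them CDKAL1 (0.59), E2F3 (0.42) and MBOAT1 (1.01) did not pass. PUDP, on the X chromosome, was higher by 0.60 ± 0.13 (adjusted p = 0.00583). XIST (1.80 ± 2.54), CHIC1 (−0.11), SMCHD1 (−0.02) and LRIF1 (−0.63) did not pass. No single array moved the count of 4195 by more than 1.5 times, the range being 2896 to 5542.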

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

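The tests of the 3 patterns described here, and the count of splits for MUM2B genes, were chosen only after the results were seen, and the other counts of splits were planned. The response to CANT1 differed between the lines for APOC2 (3.54), SFRP1 (3.46), HSBP1L1 (2.26), FSTL5 (2.01), NEFL (1.80) and AMPH (−1.56), as log2 OCM1 effect minus MUM2B effect. A limma test of that difference over 12 arrays picked them out. The same test on replicates 2 and 3 alone picked 2650 genes. Over the 12 arrays, 11 of 200 splits gave at least 6 genes, the real one included, so chance is not excluded. In wild type MUM2B SFRP1 already stood at 12.42 ± 0.50 SD, and NEFL was 3.73 higher in wild type OCM1 than in MUM2B.

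The OCM1 wild type replicate 1 array stood apart from the other OCM1 arrays, and these tests were chosen only after that was seen. RNA of another cell population, a technical explanation, fits: 15 genes were at least 8-fold above all 11 other arrays, against 0 on every other array. In addition, 67 genes typical of OCM1 were a median of 2.49 lower there than on CANT1 replicate 1. They were chosen as more than 16-fold above MUM2B on the other OCM1 arrays, CANT1 replicate 1 among them. That choice favours a lower value on the array left out, so the median is no separate test. Exchange with another array of the series is unlikely to be why it stands apart, since its highest correlation with any array was 0.847. That value cannot tell whether the labels of the 2 OCM1 replicate 1 arrays were exchanged, as the array correlates poorly under either label. It correlated at 0.816 with wild type and 0.830 with CANT1 replicates 2 and 3. CANT1 replicate 1 correlated at 0.961 and 0.955, so such an exchange is left open. Degraded RNA is unlikely too, since the ACTB 3′ minus 5′ log2 signal of the wild type array exceeded the other replicate 1 arrays by 0.239. No biological explanation was tested, as the labels describe no treatment of that array alone.

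MUM2B replicate 1 ran opposite to replicates 2 and 3, and these tests were chosen only after that was seen. Exchanged labels of the MUM2B replicate 1 arrays, a technical explanation, would fit the correlation across genes of −0.618, and the array labelled wild type correlated better with CANT1 (0.953) than with wild type arrays (0.927). The array labelled CANT1 correlated almost alike with both (0.971 with wild type and 0.967 with CANT1). RNA quality cannot be told apart either: the correlation was −0.588 after the shift between sets in OCM1 CANT1 arrays was removed, but a shift common to wild type and CANT1 arrays cancels in each difference, and quality differing between them on replicate 1 was not tested. A CANT1 effect that depends on the culture, a biological explanation, would give the same slope of −0.862, and because growth label and replicate 1 coincide it cannot be told apart from exchanged labels.

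XIST and genes bright on the OCM1 wild type replicate 1 array were higher with CANT1 in replicates 2 and 3, and these tests were chosen only after that was seen. Admixture of cells like those on that array, a technical explanation, could fit: 97.8% of 46 genes at least 8-fold above 7 arrays, wild type replicates 2 and 3 among them, were higher in OCM1 and 93.5% in MUM2B, against upper limits of 73.9% and 67.4% over 10000 random lists, and 96.1% and 90.2% of 51 genes chosen on replicate 1 arrays alone (upper limits 74.5% and 66.7%). Admixture is unlikely to be the whole of the OCM1 increases, since 51 of 168 genes raised at least 2-fold, SERPINA3 among them, were at or below their wild type level on that array. The wild type level was that of replicates 2 and 3, so differences between the labelled sets enter this count. An explanation by 1 cross-hybridising probe set is unlikely, since 5 XIST probe sets were higher in both lines. The median share of that array's signal was 2.74% over the 46 genes in OCM1 (upper quartile 4.20%) and 0.820% in MUM2B (upper quartile 1.38%). Both medians lay below all 5 XIST probe sets (4.93% to 31.0% and 1.05% to 12.3%). A spread that wide between probe sets of 1 RNA leaves a single admixed share open. SYTL2, also far higher on that array than on OCM1 CANT1 replicate 1, had a share of 9.53% in OCM1 and −0.511% in MUM2B. An effect of CANT1 on XIST, a biological explanation, cannot be told apart from admixture, because the replicate 1 difference of −5.79 rests on the OCM1 wild type array that stands apart and on MUM2B arrays whose labels are open. XIST on OCM1 CANT1 replicate 1 read 6.36, against 12.22 and 12.35 on OCM1 CANT1 replicates 2 and 3. That is 1 array with another growth label, and an exchange of its label is open, so it does not decide.

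Regrouping the same arrays gave these counts, with the test for MUM2B genes chosen only after its result was seen. Within 1 line only 10 splits exist, too few for a share under 0.05. The real counts and the highest of the other splits were 0 and 8 for MUM2B genes, 6 and 13 for MUM2B lists, 15 and 182 for OCM1 genes, 10 and 12 for OCM1 lists, 4195 and 715 for genes of the wild type lines, and 13 and 14 for their lists. As many calls came from 10, 8, 2, 5, 1 and 5 splits in that order, the real one included. For the averaged effect chance is not excluded: 18 of 200 splits gave at least the 5 genes, with 576 as the highest, and 122 gave at least the 8 lists, with 14 as the highest. For the difference chance is not excluded either, as 11 of 200 splits gave at least 6 genes, with 576 as the highest. A first draw of 100 splits had given 4 for the difference and 8 for the average, and counting all 200 was decided after that was seen. The splits with the most genes were those that exchange the replicate 1 arrays between wild type and CANT1, which points to a structure of the samples.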

How the results depend on the processing

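The tests of the labels and of the arrays in doubt were chosen only after the results were seen. The call of 0 MUM2B genes became 3032 on replicates 2 and 3, 2402 with array weights, which did not converge, and 9 without MUM2B wild type replicate 1. The 15 OCM1 genes became 28 at the larger offset, 24 without filter, 6 without set term, 2822 on replicates 2 and 3, 1 with OCM1 arrays only, 3713 with weights, 33 over all probe sets and 8 without probe sets ending in _x_at or _s_at. The 5 averaged genes became 3 with a floor, 3 without set term, 3542 on replicates 2 and 3, 3617 with weights, 10 over all probe sets and 3 at 2-fold. The 6 genes of the difference became 3 without set term, 2650 on replicates 2 and 3, 2908 with weights and 13 over all probe sets. The 4195 genes of the wild type lines became 7829 on replicates 2 and 3, 8746 with weights, 10287 over all probe sets and 2157 at 2-fold. The cause was not tested beyond the patterns described.

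Left out singly, arrays gave 5 to 139 OCM1 genes: 82 and 26 without MUM2B wild type and CANT1 replicate 1, 139 and 43 without those of OCM1, 9, 7, 8 and 9 without MUM2B wild type and CANT1 replicates 2 and 3, and 7, 6, 5 and 5 without those of OCM1. Averaged genes ranged from 1 (OCM1 CANT1 replicate 2 or 3) to 177 (MUM2B wild type replicate 1), genes of the difference from 0 (OCM1 CANT1 replicate 3) to 35 (OCM1 wild type replicate 1), and those of the wild type lines from 2896 (MUM2B wild type replicate 3) to 5542 (OCM1 wild type replicate 1). The correlation between lines of 0.0466 reversed to −0.252, −0.135 and −0.121 without MUM2B CANT1 replicate 1 or wild type replicate 2 or 3, and rose to 0.215 and 0.265 without MUM2B CANT1 replicate 3 or wild type replicate 1.

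A replicate block in place of the set term gave 7 OCM1, 3 averaged and 3 difference genes. Arrays of the same number had deviations correlating at 0.0950 to 0.623, 0.0938 to 0.465 and 0.0293 to 0.498 for replicates 1, 2 and 3. Replicates 2 against 3 of different groups gave −0.0485 to 0.554. Each group mean includes replicate 1, so these deviations hold the shift between the sets and cannot tell whether numbers pair arrays. The difference of replicate 3 minus replicate 2 is free of that shift. It correlated at −0.125 to 0.217 between groups, so the numbers were not taken to pair arrays.

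With an estimated correlation 0 of 6 MUM2B, 0 of 10 OCM1, 0 of 8 averaged and 1 of 13 wild type lists stayed called. Replicates 2 and 3 called 10 lists in MUM2B and reversed G2/M in MUM2B (adjusted p 0.115), pigment and ribosomal protein genes in OCM1 (0.133 and 0.783) and on average (0.796 and 0.837), and invasion and interferon genes between wild type lines (0.747 and 0.823). Of 222 list alternatives 164 kept the call, 51 were weaker and 7 reversed. Of 915 for named genes 769 kept the call, 137 were weaker, 9 stronger and 0 reversed. A call that stayed absent counted as kept, and a sign change where neither fit passed counted as weaker. XIST in OCM1, not called with all arrays, ran from −0.49 to 5.88 over the alternatives. The tally includes the named genes of the wild type lines, whose calls were all kept. The 5 lists of the difference, not in that tally, were all lost with an estimated correlation, and replicates 2 and 3 reversed pigment and G1/S genes there (0.0854 and 0.412).

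Alternatives added after the data were seen gave 3 averaged genes on the deposited scale. A set term per line gave 120 OCM1, 17 averaged, 11 difference and 2342 wild type genes. Without both wild type replicate 1 arrays, 2079 MUM2B, 1230 OCM1, 2194 averaged, 1278 difference and 7305 wild type genes were called and r was 0.255.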

Other observations

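The lists here come from replicates 2 and 3, and describing them was chosen only after those values were seen. The lists of p53 targets, heat shock genes, Wnt and TGF-β components and uveal melanoma class genes were called there on the average of both lines, none with an estimated correlation. Of 25 p53 targets 14 rose and 1 fell on average (camera adjusted p = 0.00866; adjusted p = 0.354 with an estimated correlation), among them TP53INP1 (1.15 ± 0.15), PHLDA3 (0.56 ± 0.09) and the cell cycle inhibitor CDKN1A (0.44 ± 0.08), and their median was −0.63 on replicate 1. In single lines the p53 list was not called (adjusted p = 0.0863 in MUM2B and 0.0923 in OCM1). Heat shock genes fell in 10 of 19 with 1 rising (adjusted p = 0.00107; adjusted p = 0.385 with an estimated correlation), CHORDC1 by 0.81 ± 0.10, while BAG3 rose by 0.52 ± 0.07. Heat shock genes were called in OCM1 and not in MUM2B (adjusted p = 0.378), and the difference of effects was called (adjusted p = 0.0210; adjusted p = 0.656 with an estimated correlation). Wnt and TGF-β components rose in 12 of 31 and fell in 3 (adjusted p = 0.00798; adjusted p = 0.385 with an estimated correlation). The receptor FZD7 (0.98 ± 0.09) and SFRP1 (1.57 ± 0.07) rose and ID3, a target of BMP signalling, fell by 0.90 ± 0.07. Among uveal melanoma class genes, whose loss or gain marks metastatic risk, 6 of 11 rose on average (adjusted p = 0.00107; adjusted p = 0.385 with an estimated correlation), SATB1 by 1.11 ± 0.11, with a median of −0.30 on replicate 1. The members were not split by the direction in which they mark risk, so this rise gives no shift of class. The Wnt and the class list were not called in OCM1 (adjusted p = 0.312 each).

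Angiogenesis genes were called neither in a line (adjusted p = 0.106 in MUM2B and 0.312 in OCM1) nor in the difference (adjusted p = 0.902). Within the list VEGFC rose in both lines, by 1.10 ± 0.14 in MUM2B and 1.33 ± 0.14 in OCM1. In OCM1 the angiogenesis inhibitor SERPINF1 rose by 1.90 ± 0.13 and the growth factor PDGFC by 1.58 ± 0.10, while the Notch ligand JAG1 fell by 0.85 ± 0.10. Hypoxia and glycolysis genes were lower in the OCM1 effect than in the MUM2B effect in 9 of 35 cases and higher in 0 (adjusted p = 0.00681; adjusted p = 0.586 with an estimated correlation), ENO2 by −0.91 ± 0.13 and HK2 by −0.59 ± 0.14, with a median of 0.65 on replicate 1.

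OCM1 CANT1 replicate 1 resembled CANT1 replicates 2 and 3 in APOC2, at 10.34 against 11.08 and 11.01, but wild type in XIST, at 6.36 against 6.44 and 6.37 on wild type replicates 2 and 3. TYRP1, at 13.98, matched wild type (13.73 and 13.78) more than CANT1 (11.40 and 11.90).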
